A study of Mus musculus with 12 samples.

How the data were processed

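RNA from RAW264.7 mouse macrophages was hybridised to 12 Affymetrix-type expression arrays, 3 each for Vav1 knockout, Vav2 knockout, Vav3 knockout and wildtype cells, with total RNA, biotin-labelled cRNA and no treatment per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited table holds 1 normalized intensity per probe set and array. RMA is the one tool named, per the submitters' processing notes, and its version is not given in the sources used here. RMA usually returns log2 values, whereas the deposited intensities are linear, running up to 13498, and whether they were transformed back is not given in the sources used here. The planned test assumed log2 values and allowed for linear ones, so log2(intensity + 1) was tested. This offset understates fold changes of dim genes. Where every array of 1 group read under its array median, the fold change is given as a bound, with that median in place of lower values. Where only some arrays did, the plain value is given and is less certain. Examples are Gbp8 and Cnrip1 in the Vav3 knockout, Car6 and Lcn2 in the Vav2 knockout and Ifi44l in both. Detection calls, scan dates and background values were not analysed here, so no batch could be tested from the labels.

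Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several, and 9211 were not listed there and are unnamed here. Symbols were set against a RefSeq gene table, in which the gene identifiers of 34754 probe sets matched. Genes were named from probe sets with 1 symbol only. A probe set passed the filter when at least 3 of the 12 arrays lay above that array's median, which 23626 did, and each gene was represented by its probe set with the highest mean, leaving 11962 genes. Probe sets whose names end in s_at or x_at can bind transcripts of related genes. No coordinates are given because no genome build is named.

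Differences were tested with limma 3.58.1 in R 4.3.3, by 1 linear model of 4 group means over all 12 arrays with 8 residual degrees of freedom and empirical Bayes variances. All groups entered the fit so that they share 1 estimate of spread. The wildtype arrays varied less than the knockout arrays, so this estimate lies above the spread of the wildtype arrays and can lie below that of the knockout arrays. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. Vav probe sets were tested in a fit over all probe sets without the filter. The 40 gene lists were fixed before the data were examined. The results of 2 of them are not reported here. Lists of histones, of epithelial cells and of neutrophils and mast cells had fewer than 5 tested members and were left out. The other 37 were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction.

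The genes named in the text follow a rule set before the data were examined. It takes Vav1, Vav2 and Vav3, and per knockout the 8 highest and 8 lowest log2 fold changes among called genes whose 3 knockout arrays all lay on 1 side of the wildtype arrays. It adds up to 4 called members of each list described, or the 2 brightest where none was called, the 8 largest shared rises and falls, and 4 genes in each direction per pair of knockouts. Unnamed gene models were left out.

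The procedure was tested on simulated data for all 11962 genes, with the observed means and 200 changed genes per comparison. Each gene had its wildtype spread and 1 spread for all knockout arrays, averaged over the knockouts, although the knockouts differed in spread. A further gene list was shifted by a smaller amount and was not counted as false where called. For the Vav1 knockout against wildtype it recovered 43.3% of genes changed by 0.5 log2 units, 88.1% of those changed by 1 and 98.5% of those changed by 2. For the Vav1 against the Vav2 knockout the shares were 46.3%, 77.6% and 97.0%, and 30 of 183 calls were false, a share above the threshold of 0.05. False calls were 38 of 194 for Vav1 against Vav3, 31 of 187 for Vav2 against Vav3, and 3 of 157, 5 of 163 and 11 of 169 for the Vav1, Vav2 and Vav3 knockouts against wildtype. The simulation draws genes independently, and its many planted changes ease the adjusted threshold. Its shares can therefore overstate recovery where few genes pass, as between knockouts. The alternatives tried concern the filter, the probe set rule, normalization, the arrays in the fit, the variance model, array weights, a replicate block, thresholds, the list test and leaving out each array. All 3 pairs of arrays with 1 number correlated above 0.1 only between the Vav2 and Vav3 knockouts, where they correlated at 0.238, 0.522 and 0.164 and 4 of 6 arrays correlated best with their own number. This pairing comes from the values and not from the labels. Added after the data were examined were no offset, a replicate block for these 6 arrays alone, weights shared within the knockout and wildtype arrays, and leaving out the Vav1_KO 3 and Vav2_KO 2 arrays. The iterative estimate of array weights stopped before its convergence tolerance in some fits.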

Results

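Gene expression was measured in RAW264.7 cells, an established mouse macrophage line, on 12 arrays. Vav1, Vav2 or Vav3 had been knocked out in 9 of the samples, 3 for each gene, and 3 samples were wildtype cells. Vav proteins are signalling proteins that act downstream of tyrosine kinases. The labels name no treatment. Each array gave intensities for 45101 probe sets, with medians between 14.9 and 15.6 per array, and 11962 genes passed the filter on dim probe sets. The number of arrays limits the precision, and the 95% interval of a log2 fold change had a median half-width of 0.26. The labels do not say whether arrays of 1 group came from separate cultures or clones, so p-values measure only the spread between these arrays, which may be technical.

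The targeted genes were examined first. Vav1 intensity was 30.1 ± 16.7 in the Vav1 knockout and 269.7 ± 5.12 in wildtype cells (SD, n = 3 each). The log2 fold change was -3.32 ± 0.40 (SE, limma adjusted p = 9.32e-04). A second Vav1 probe set changed by -1.55 ± 0.23 (SE, adjusted p = 0.00261). Vav3 intensity was 43.4 ± 1.81 in the Vav3 knockout against 245 ± 10.4 in wildtype cells (SD, n = 3 each), a log2 fold change of -2.47 ± 0.19 (SE, adjusted p = 8.70e-05). Both other Vav3 probe sets were also lower, at adjusted p = 2.84e-05 and 0.00308. Vav2 signal was low, though its brightest probe set, between 19.8 and 31.7 on single arrays, lay above every array median. This probe set read 27.5 ± 3.57 in the Vav2 knockout and 23.6 ± 3.39 in wildtype cells (SD, n = 3 each). The log2 difference was 0.21 ± 0.12 (SE, adjusted p = 0.342). The other Vav2 probe sets differed by -0.44 ± 0.20 (adjusted p = 0.218) and -0.15 ± 0.11 (adjusted p = 0.485). These arrays therefore do not check the Vav2 label, and the position of the probes relative to the edits is not given in the sources used here. Vav1 intensity was 148 ± 63.0 in the Vav2 knockout and 165 ± 22.6 in the Vav3 knockout (SD, n = 3 each). These were 54.9% and 61.3% of wildtype, and neither difference passed the test (adjusted p = 0.180 and 0.324).

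**Figure D1:**
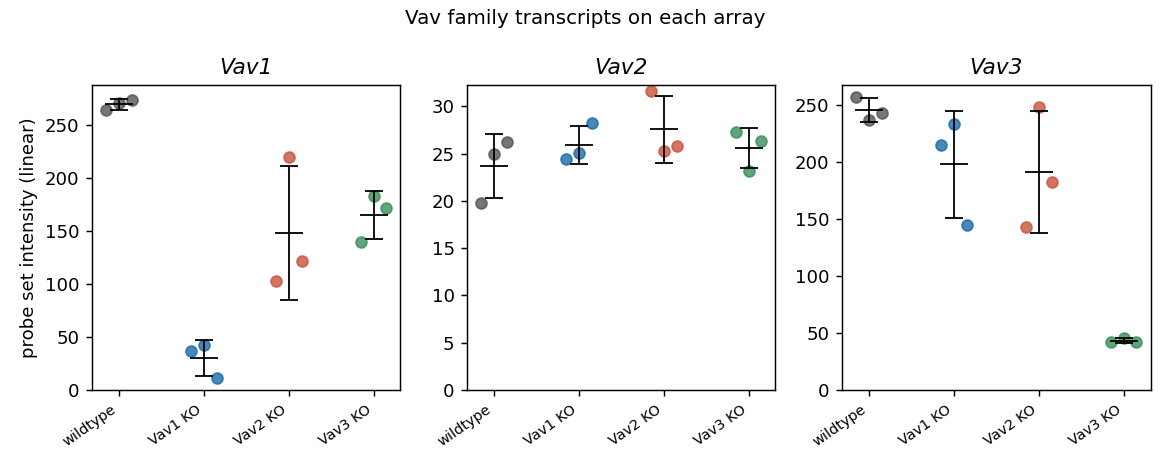
Intensity of the brightest probe set of Vav1, Vav2 and Vav3 on each array (linear scale, y axis) by group (x axis), with points for arrays and black marks for the mean and SD of 3 arrays. Vav1 averaged 30.1 in its knockout against 269.7 in wildtype cells and Vav3 43.4 against 245, while Vav2 read 27.5 against 23.6.

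The wildtype arrays lay closer together than the knockout arrays. The median SD of a gene across 3 arrays was 0.0669 log2 units in wildtype cells, 0.144 in the Vav1, 0.186 in the Vav2 and 0.102 in the Vav3 knockout. The first principal component held 62.2% of the variance and placed the wildtype arrays between -34.1 and -32.3. Knockout arrays ranged from -1.74 to 34.6 for Vav1, from -16.0 to 34.4 for Vav2 and from -2.96 to 12.8 for Vav3. Of 45 probe sets for bacterial or phage control transcripts, called bacterial here, 16 had all 9 knockout arrays above or all below the wildtype arrays, 13 above and 3 below. These transcripts hold no cell RNA. Several probe sets share 1 transcript, and the 13 above were of bioB, lys, phe and thr and the 3 below of cre. The 16 are therefore not independent. Chance gives 0.909% for 1 probe set and the observed share was 35.6%, against 30.8% of the tested genes by the same rule.

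**Figure D2:**
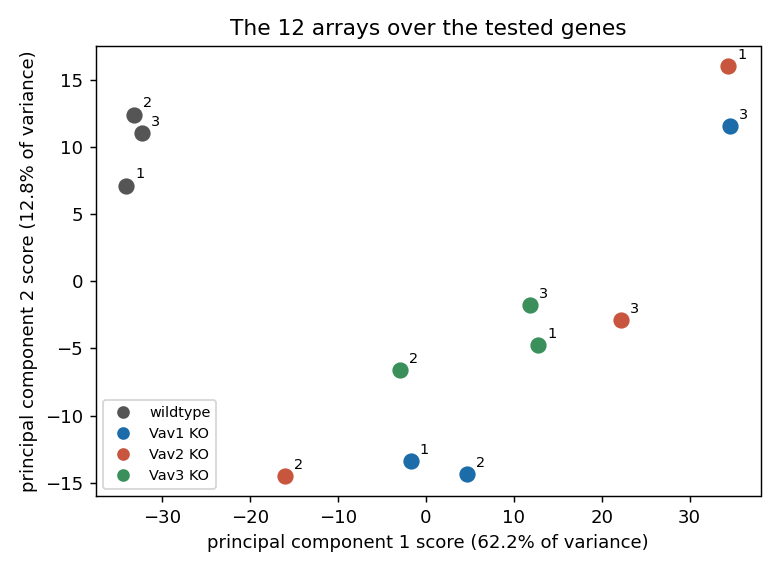
Scores of the 12 arrays on the first (x axis, 62.2% of variance) and second (y axis, 12.8%) principal component of log2 intensities of the tested genes, with colours for groups and numbers for replicates. The wildtype arrays lie together at the left, from -34.1 to -32.3, and the knockout arrays spread from -16.0 to 34.6 with the genotypes intermixed.

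The Vav1 knockout was compared with wildtype cells. Gpnmb, a transmembrane glycoprotein of lysosomes and macrophages, fell from 1068 ± 111 to 41.6 ± 31.7 intensity units (SD, n = 3 each). Its log2 fold change was -4.89 ± 0.51 (SE, adjusted p = 3.99e-04). Among interferon-induced genes, Rtp4 changed by -4.73 ± 0.53, Usp18, which removes ISG15 from proteins, by -4.18 ± 0.56, and Ifi202b by -3.60 ± 0.46. Lower levels were also found for Gbp8 (at least 2.38 lower), Gkap1 (-3.41) and Lgals9 (-3.20), where a bound in log2 units is given for a gene whose dimmer group lay under the array median on every array. Scel, which encodes sciellin, rose from 44.4 ± 6.60 to 384 ± 125 (SD, n = 3 each), a log2 fold change of 3.05 ± 0.44 (SE, adjusted p = 0.00192). Higher levels were also found for Fosb (at least 2.16 higher), Dusp1 (2.28) and Fos (1.63), which respond early to stimuli. The uracil-DNA glycosylase gene Ung (2.42), the lipoprotein receptor gene Lrp8 (1.95) and the cyclin E genes Ccne2 (1.90) and Ccne1 (1.61) rose as well. In all, 1876 genes rose and 1077 fell at an adjusted p under 0.05, of which 359 changed by at least 1 log2 unit.

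Gene lists were tested next, and 5 were called as higher in the Vav1 knockout by camera, though not every member passed. Of 38 DNA replication genes, 35 rose and 0 fell (36 and 0 adjusted over the list alone), including Ung (2.42) and Ccne2 (1.90). For DNA replication genes, camera gave adjusted p = 2.85e-16, and adjusted p = 0.365 with an estimated correlation. Of 39 mitosis genes, 19 rose and 0 fell (30 and 0 adjusted over the list alone), including Cenpa (0.94), Birc5 (0.89) and Kif20a (0.87). For mitosis genes, camera gave adjusted p = 4.45e-09, and adjusted p = 0.366 with an estimated correlation. Of 20 cholesterol biosynthesis genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone), including Idi1 (1.25), Stard4 (1.15) and Insig1 (1.14). For cholesterol biosynthesis genes, camera gave adjusted p = 1.04e-06, and adjusted p = 0.365 with an estimated correlation. Of 42 oxidative phosphorylation genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), including Ndufa4 (0.76) and Ndufb8 (0.60). For oxidative phosphorylation genes, camera gave adjusted p = 6.40e-05, and adjusted p = 0.438 with an estimated correlation. Of 16 heat shock genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), including Ahsa1 (1.10) and Stip1 (0.90). For heat shock genes, camera gave adjusted p = 0.00666, and adjusted p = 0.504 with an estimated correlation. Ahsa1 and Stip1 encode cofactors of the chaperone Hsp90.

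Interferon, macrophage, receptor and effector lists were called as lower in the Vav1 knockout by camera, although most members of some did not pass. Of 41 type I interferon-stimulated genes, 0 rose and 31 fell (1 and 33 adjusted over the list alone), including Rtp4 (-4.73), Usp18 (-4.18), Ifi44l (at least 1.73 lower) and Xaf1 (-2.74). For type I interferon-stimulated genes, camera gave adjusted p = 8.06e-20, and adjusted p = 0.256 with an estimated correlation. Of 19 interferon-gamma-induced GTPase and class II genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone), including Irgm2 (-2.08), Igtp (-1.32) and Cd74 (-1.15). For interferon-gamma-induced GTPase and class II genes, camera gave adjusted p = 0.00141, and adjusted p = 0.256 with an estimated correlation. Cd74 encodes the invariant chain of class II molecules. Of 28 macrophage identity genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone), including Cd53 (-0.91), Csf2ra (-0.85) and Itgam (-0.78). For macrophage identity genes, camera gave adjusted p = 0.00129, and adjusted p = 0.256 with an estimated correlation. Of 25 phagocytic and scavenger receptor genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), including Fcgr3 (-1.58) and Fcgr4 (-1.39). For phagocytic and scavenger receptor genes, camera gave adjusted p = 0.00360, and adjusted p = 0.256 with an estimated correlation. Fcgr3 and Fcgr4 encode Fc receptors. Of 29 integrin and adhesion receptor genes, 0 rose and 10 fell (2 and 12 adjusted over the list alone), including Itgal (-1.02) and Itgam (-0.78). For integrin and adhesion receptor genes, camera gave adjusted p = 0.00290, and adjusted p = 0.256 with an estimated correlation. Of 14 NADPH oxidase and antimicrobial genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone), including Slpi (-1.99) and Lcn2 (-1.78). For NADPH oxidase and antimicrobial genes, camera gave adjusted p = 0.00381, and adjusted p = 0.365 with an estimated correlation. Alongside these groups, 16 of 45 bacterial control probe sets also separated knockout from wildtype arrays.

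Further lists were called as lower in the Vav1 knockout by camera, although many of their members were not called. Of 31 NF-kB target and cytokine genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone), including Il1rn (-2.41), Ptgs2 (-1.77) and Il23a (-1.66). For NF-kB target and cytokine genes, camera gave adjusted p = 0.00359, and adjusted p = 0.504 with an estimated correlation. Il1rn encodes the receptor antagonist of interleukin 1. Of 40 lysosome genes, 0 rose and 8 fell (0 and 6 adjusted over the list alone), including Gpnmb (-4.89), Atp6v0d1 (-0.74) and Ctsl (-0.67). For lysosome genes, camera gave adjusted p = 2.95e-05, and adjusted p = 0.504 with an estimated correlation. Of 33 ATF4 and amino acid stress genes, 0 rose and 4 fell (0 and 3 adjusted over the list alone), including Aldh1l2 (-2.42) and Eprs (-0.95). For ATF4 and amino acid stress genes, camera gave adjusted p = 6.25e-05, and adjusted p = 0.595 with an estimated correlation. Of 21 matrix remodelling genes, 1 rose and 5 fell (1 and 9 adjusted over the list alone), including Plau (-1.36) and Ctsl (-0.67). For matrix remodelling genes, camera gave adjusted p = 0.0102, and adjusted p = 0.256 with an estimated correlation. Of 6 complement genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone), including C3ar1 (-1.15). For complement genes, camera gave adjusted p = 0.0311, and adjusted p = 0.256 with an estimated correlation. Of 53 actin and podosome genes, 4 rose and 13 fell (6 and 13 adjusted over the list alone), including Marcksl1 (-1.30), Tmsb10 (-0.79), Coro1c (0.80) and Tagln2 (0.78). For actin and podosome genes, camera gave adjusted p = 0.0411, and adjusted p = 0.366 with an estimated correlation. Camera with a preset correlation called 18 of 37 lists in the Vav1 knockout, fry called 20, and camera with an estimated correlation called 0. The lists called by camera and not by fry were those of NF-kB target and cytokine (0.0801), ATF4 and amino acid stress (0.189) and lysosome (0.0711) genes (fry adjusted p). After arrays were shifted to an equal median, 2 of the lists called by camera, of actin and podosome and complement genes, were no longer called, each with an adjusted p just above the threshold. Called genes that rose made up 63.5% with values as deposited and 44.7% after arrays were shifted to an equal median over the tested genes. The count of 2953 called genes became 1815 without Vav1_KO 3, 1873 without WT 1, 1380 without WT 2 and 1538 without WT 3, and 6642 with array weights.

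**Figure D3:**
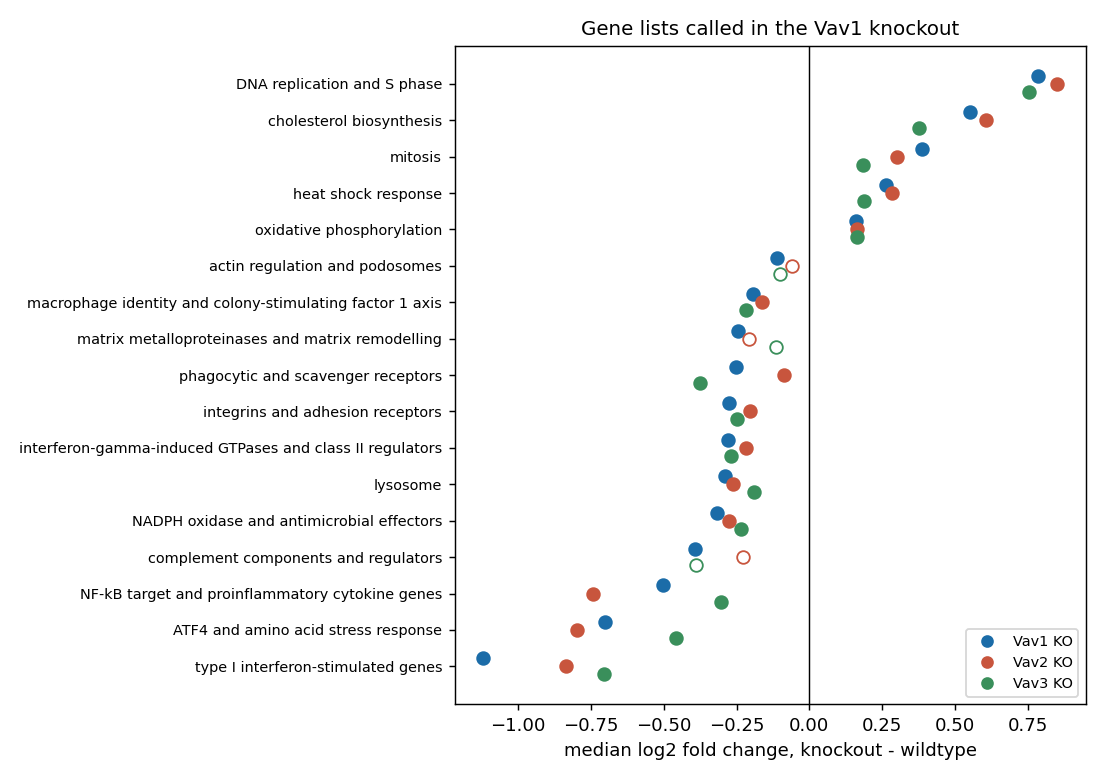
Median log2 fold change (x axis) of the tested members of 17 gene lists called in the Vav1 knockout (y axis), for each knockout against wildtype cells, with filled points where camera with a preset correlation passed and open points where it did not. Replication genes lie highest, at 0.78, 0.85 and 0.75 for the Vav1, Vav2 and Vav3 knockouts, and type I interferon-stimulated genes lowest, at -1.12, -0.83 and -0.71.

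The Vav2 knockout was compared with the same wildtype arrays. Gpnmb fell from a mean of 1068 to 48.2 intensity units, a log2 fold change of -4.60 ± 0.51 (SE, n = 3 each, limma adjusted p = 7.76e-04). The secreted carbonic anhydrase gene Car6 changed by -3.91 ± 0.82 (from arrays at 7.57, 40.2 and 12.4), and the guanylate-binding protein gene Gbp8 was at least 2.38 lower. Lower levels were also found for Ifi202b (-3.47), Abtb2 (at least 1.99 lower), Mcoln2 (at least 2.15 lower), Rtp4 (-3.11) and Hebp1 (-2.96). Ung rose from 37.2 ± 3.66 to 248 ± 118 (SD, n = 3 each), a log2 fold change of 2.56 ± 0.40 (SE, adjusted p = 0.00329). Other genes that rose were Dipk2a (2.28), Mkx (at least 0.98 higher), Ccne2 (2.13), Cd48 (2.07), Lrp8 (2.04), Scel (1.95) and Treml4 (at least 0.81 higher). In all, 1788 genes rose and 1135 fell, of which 360 changed by at least 1 log2 unit.

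The lists called as higher in the Vav2 knockout by camera were those called as higher in the Vav1 knockout, and not every member passed. Of 38 DNA replication genes, 34 rose and 0 fell (36 and 0 adjusted over the list alone), including Ccne2 (2.13) and Cdc6 (1.55). For DNA replication genes, camera gave adjusted p = 3.98e-16, and adjusted p = 0.333 with an estimated correlation. Of 20 cholesterol biosynthesis genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), including Idi1 (1.45) and Lss (0.96). For cholesterol biosynthesis genes, camera gave adjusted p = 2.86e-08, and adjusted p = 0.333 with an estimated correlation. Of 39 mitosis genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), including Aurkb (0.79) and Birc5 (0.79). For mitosis genes, camera gave adjusted p = 1.65e-04, and adjusted p = 0.486 with an estimated correlation. Of 42 oxidative phosphorylation genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone), including Ndufa4 (0.67) and Ndufa8 (0.41). For oxidative phosphorylation genes, camera gave adjusted p = 2.03e-04, and adjusted p = 0.486 with an estimated correlation. Of 16 heat shock genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), including Ahsa1 (1.08) and Hsph1 (1.02). For heat shock genes, camera gave adjusted p = 0.00113, and adjusted p = 0.476 with an estimated correlation.

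Lists of interferon, cytokine, ATF4 and lysosome genes were called as lower in the Vav2 knockout by camera, although most members passed only for the type I interferon list. Of 41 type I interferon-stimulated genes, 0 rose and 29 fell (1 and 31 adjusted over the list alone), including Usp18 (-2.69), Ifi44l (-2.19) and Ddx58 (-1.93). For type I interferon-stimulated genes, camera gave adjusted p = 2.11e-14, and adjusted p = 0.333 with an estimated correlation. Ddx58 encodes the RNA sensor RIG-I. Of 19 interferon-gamma-induced GTPase and class II genes, 1 rose and 8 fell (2 and 8 adjusted over the list alone), including Irgm2 (-1.61) and Cd74 (-1.09). For interferon-gamma-induced GTPase and class II genes, camera gave adjusted p = 0.0118, and adjusted p = 0.333 with an estimated correlation. Of 31 NF-kB target and cytokine genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), including Il1rn (-2.52), Cd40 (-2.19) and Il23a (-2.09). For NF-kB target and cytokine genes, camera gave adjusted p = 1.40e-04, and adjusted p = 0.476 with an estimated correlation. Of 33 ATF4 and amino acid stress genes, 0 rose and 5 fell (0 and 2 adjusted over the list alone), including Aldh1l2 (-2.57) and Slc7a11 (-1.05). For ATF4 and amino acid stress genes, camera gave adjusted p = 2.32e-05, and adjusted p = 0.508 with an estimated correlation. Slc7a11 encodes a cystine transporter. Of 40 lysosome genes, 0 rose and 3 fell (0 and 2 adjusted over the list alone), including Gpnmb (-4.60), Ctsl (-0.59) and Ctsd (-0.51). For lysosome genes, camera gave adjusted p = 2.75e-04, and adjusted p = 0.486 with an estimated correlation.

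Receptor and effector lists were also called as lower in the Vav2 knockout, with most members not called. Of 14 NADPH oxidase and antimicrobial genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone), including Lcn2 (-2.53) and Slpi (-1.75). For NADPH oxidase and antimicrobial genes, camera gave adjusted p = 0.00428, and adjusted p = 0.333 with an estimated correlation. Of 28 macrophage identity genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone), including Itgam (-1.02) and Ptprc (-0.78). For macrophage identity genes, camera gave adjusted p = 0.00512, and adjusted p = 0.333 with an estimated correlation. Of 29 integrin and adhesion receptor genes, 0 rose and 9 fell (2 and 9 adjusted over the list alone), including Itgal (-1.09) and Itga7 (-0.77). For integrin and adhesion receptor genes, camera gave adjusted p = 0.0158, and adjusted p = 0.333 with an estimated correlation. Of 25 phagocytic and scavenger receptor genes, 1 rose and 6 fell (1 and 7 adjusted over the list alone), including Fcgr3 (-2.18) and Clec7a (-1.77). For phagocytic and scavenger receptor genes, camera gave adjusted p = 0.0327, and adjusted p = 0.333 with an estimated correlation. Alongside these groups, 16 of 45 bacterial control probe sets also separated knockout from wildtype arrays. Camera with a preset correlation called 15 lists in the Vav2 knockout, fry called 18, and camera with an estimated correlation called 0. The lists called by camera and not by fry were those of mitosis (0.0553), ATF4 and amino acid stress (0.156) and lysosome (0.121) genes (fry adjusted p). Called genes that rose made up 61.2% with values as deposited and 49.0% after the median shift. The count of 2923 called genes became 1591 without Vav2_KO 1, 5397 without Vav2_KO 2, 1111 without Vav2_KO 3, 1798 without WT 1, 1175 without WT 2 and 1326 without WT 3. It was 6181 without both Vav1_KO 3 and Vav2_KO 2, a choice made after seeing the data, and 1544 when only the arrays compared were fitted.

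The Vav3 knockout was compared with wildtype cells in the same way. Gpnmb fell from 1068 ± 111 to 54.6 ± 23.8 (SD, n = 3 each), a log2 fold change of -4.35 ± 0.51 (SE, adjusted p = 0.00140). The nuclear noncoding RNA Neat1 changed by -3.29 ± 0.82 and Cnrip1 by -3.05 ± 0.40, while the cation channel gene Mcoln2 was at least 2.13 lower and the prostaglandin E2 receptor gene Ptger2 at least 0.98 lower. Lower levels were also found for Gbp8 (-3.47, from arrays at 3.54, 17.0 and 4.37), Car6 (-2.89) and Abtb2 (at least 1.97 lower). Scel rose from 44.4 ± 6.60 to 428 ± 194 (SD, n = 3 each), a log2 fold change of 3.12 ± 0.44 (SE, adjusted p = 0.00266). Other genes that rose were Ung (2.46), Ccne2 (2.05), Dipk2a (1.95), Lrp8 (1.76), Mkx (at least 0.52 higher), Cd48 (1.65) and Dusp1 (1.63). In all, 1363 genes rose and 1113 fell, of which 263 changed by at least 1 log2 unit.

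The same 5 lists were called as higher in the Vav3 knockout by camera, and most members passed only for DNA replication. Of 38 DNA replication genes, 34 rose and 0 fell (36 and 0 adjusted over the list alone), including Ccne1 (1.48) and Gins2 (1.52). For DNA replication genes, camera gave adjusted p = 3.29e-16, and adjusted p = 0.459 with an estimated correlation. Of 42 oxidative phosphorylation genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone), including Ndufa4 (0.71), Ndufb8 (0.63) and Ndufv2 (0.49). For oxidative phosphorylation genes, camera gave adjusted p = 1.55e-05, and adjusted p = 0.459 with an estimated correlation. Of 20 cholesterol biosynthesis genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone), including Idi1 (1.27), Stard4 (1.04) and Dhcr7 (0.86). For cholesterol biosynthesis genes, camera gave adjusted p = 4.16e-05, and adjusted p = 0.459 with an estimated correlation. Of 39 mitosis genes, 11 rose and 0 fell (14 and 0 adjusted over the list alone), including Cenpa (0.90) and Ccna2 (0.71). For mitosis genes, camera gave adjusted p = 0.00892, and adjusted p = 0.689 with an estimated correlation. Of 16 heat shock genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), including Ahsa1 (1.08) and Stip1 (0.89). For heat shock genes, camera gave adjusted p = 0.0240, and adjusted p = 0.686 with an estimated correlation.

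Lists of interferon, p53 target, receptor and macrophage genes were called as lower in the Vav3 knockout by camera, although most p53 target, receptor and macrophage genes did not pass. Of 41 type I interferon-stimulated genes, 0 rose and 28 fell (1 and 30 adjusted over the list alone), including Rtp4 (-2.61), Ifi44l (-1.99) and Irf7 (-1.84). For type I interferon-stimulated genes, camera gave adjusted p = 1.92e-13, and adjusted p = 0.459 with an estimated correlation. Irf7 encodes a transcription factor of interferon genes. Of 19 interferon-gamma-induced GTPase and class II genes, 2 rose and 8 fell (2 and 8 adjusted over the list alone), including Irgm2 (-1.32) and Psmb9 (0.79). For interferon-gamma-induced GTPase and class II genes, camera gave adjusted p = 0.0301, and adjusted p = 0.459 with an estimated correlation. Psmb9 encodes a subunit of the immunoproteasome. Of 25 p53 target genes, 2 rose and 6 fell (2 and 8 adjusted over the list alone), including Trp53inp1 (-1.49), Bbc3 (-1.25) and Plk2 (-1.25). For p53 target genes, camera gave adjusted p = 0.0143, and adjusted p = 0.459 with an estimated correlation. The adjusted p of this list was 0.0577 in the Vav1 and 0.128 in the Vav2 knockout, and the difference between knockouts was not tested. Of 25 phagocytic and scavenger receptor genes, 1 rose and 6 fell (1 and 8 adjusted over the list alone), including Fcgr3 (-1.66) and Fcgr4 (-1.64). For phagocytic and scavenger receptor genes, camera gave adjusted p = 0.00892, and adjusted p = 0.459 with an estimated correlation. Of 28 macrophage identity genes, 2 rose and 7 fell (2 and 9 adjusted over the list alone), including Itgam (-0.99) and Csf2ra (-0.89). For macrophage identity genes, camera gave adjusted p = 0.00892, and adjusted p = 0.459 with an estimated correlation.

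Adhesion, effector, lysosome, cytokine and ATF4 lists were also called as lower in the Vav3 knockout, with most members not called. Of 29 integrin and adhesion receptor genes, 0 rose and 5 fell (0 and 8 adjusted over the list alone), including Itgal (-0.96) and Alcam (-0.42). For integrin and adhesion receptor genes, camera gave adjusted p = 0.00892, and adjusted p = 0.459 with an estimated correlation. Of 14 NADPH oxidase and antimicrobial genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone), including Slpi (-2.17) and Lcn2 (-1.92). For NADPH oxidase and antimicrobial genes, camera gave adjusted p = 0.00892, and adjusted p = 0.459 with an estimated correlation. Of 40 lysosome genes, 0 rose and 4 fell (0 and 2 adjusted over the list alone), including Ctsl (-0.55) and Lamp2 (-0.36). For lysosome genes, camera gave adjusted p = 0.00199, and adjusted p = 0.686 with an estimated correlation. Of 31 NF-kB target and cytokine genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone), including Il1rn (-2.44), Il23a (-1.94) and Tnf (0.97). For NF-kB target and cytokine genes, camera gave adjusted p = 0.0163, and adjusted p = 0.686 with an estimated correlation. Of 33 ATF4 and amino acid stress genes, 1 rose and 2 fell (0 and 2 adjusted over the list alone), including Eprs (-0.90), Wars (-0.77) and Psat1 (0.27). For ATF4 and amino acid stress genes, camera gave adjusted p = 0.00892, and adjusted p = 0.690 with an estimated correlation. Alongside these groups, 16 of 45 bacterial control probe sets also separated knockout from wildtype arrays. Camera with a preset correlation called 16 lists in the Vav3 knockout, fry called 17, and camera with an estimated correlation called 0. The lists called by camera and not by fry were those of NF-kB target and cytokine (0.164), mitosis (0.164), ATF4 and amino acid stress (0.355), heat shock (0.0833) and lysosome (0.176) genes (fry adjusted p). Called genes that rose made up 55.0% with values as deposited and 49.5% after the median shift. The count of 2476 called genes became 939 without Vav3_KO 1, 1040 without Vav3_KO 3, 1226 without WT 1, 829 without WT 2 and 918 without WT 3. It was 6568 with array weights and 5439 when only the arrays compared were fitted.

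Across the 3 knockouts, 1109 genes rose and 665 fell in every comparison with wildtype cells, and 0 genes were called in opposite directions in any pair of knockouts. Among the largest shared rises, in the order Vav1, Vav2 and Vav3 knockout, were Ung (2.42, 2.56 and 2.46), Scel (3.05, 1.95 and 3.12), Ccne2 (1.90, 2.13 and 2.05) and Lrp8 (1.95, 2.04 and 1.76). Cd48 (1.56, 2.07 and 1.65), Fubp1 (1.48, 1.57 and 1.42) and Mybl2 (1.51, 1.47 and 1.44), which encodes a cell cycle transcription factor, also rose. Shared falls included Gpnmb (-4.89, -4.60 and -4.35), Rtp4 (-4.73, -3.11 and -2.61) and Car6 (-2.74, -3.91 and -2.89), and Mcoln2 and Ptger2 also fell, to levels under the array median on every knockout array, so that their falls have only lower bounds. Independent lists of these sizes would share 32.0 genes up and 9.51 down. In 50 simulations of unchanged groups against the same wildtype arrays, with genes drawn independently, limma gave at most 0 shared genes. Such draws hold no offset common to the wildtype arrays. Over genes, which are not independent replicates, the fold changes correlated at r = 0.936 for the Vav1 and Vav2 knockouts, 0.902 for Vav1 and Vav3 and 0.922 for Vav2 and Vav3. The simulated means were 0.116, 0.121 and 0.122. The covariances were 0.189, 0.166 and 0.169, against 0.00289, 0.00301 and 0.00303 in the simulations. The 3 wildtype arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls. The count of 1774 shared genes became 3061 without Vav2_KO 2, 926 without Vav2_KO 3, 776 without Vav3_KO 1, 871 without Vav3_KO 3, 953 without WT 1, 598 without WT 2 and 670 without WT 3, and 3100 without both Vav1_KO 3 and Vav2_KO 2.

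**Figure D4:**
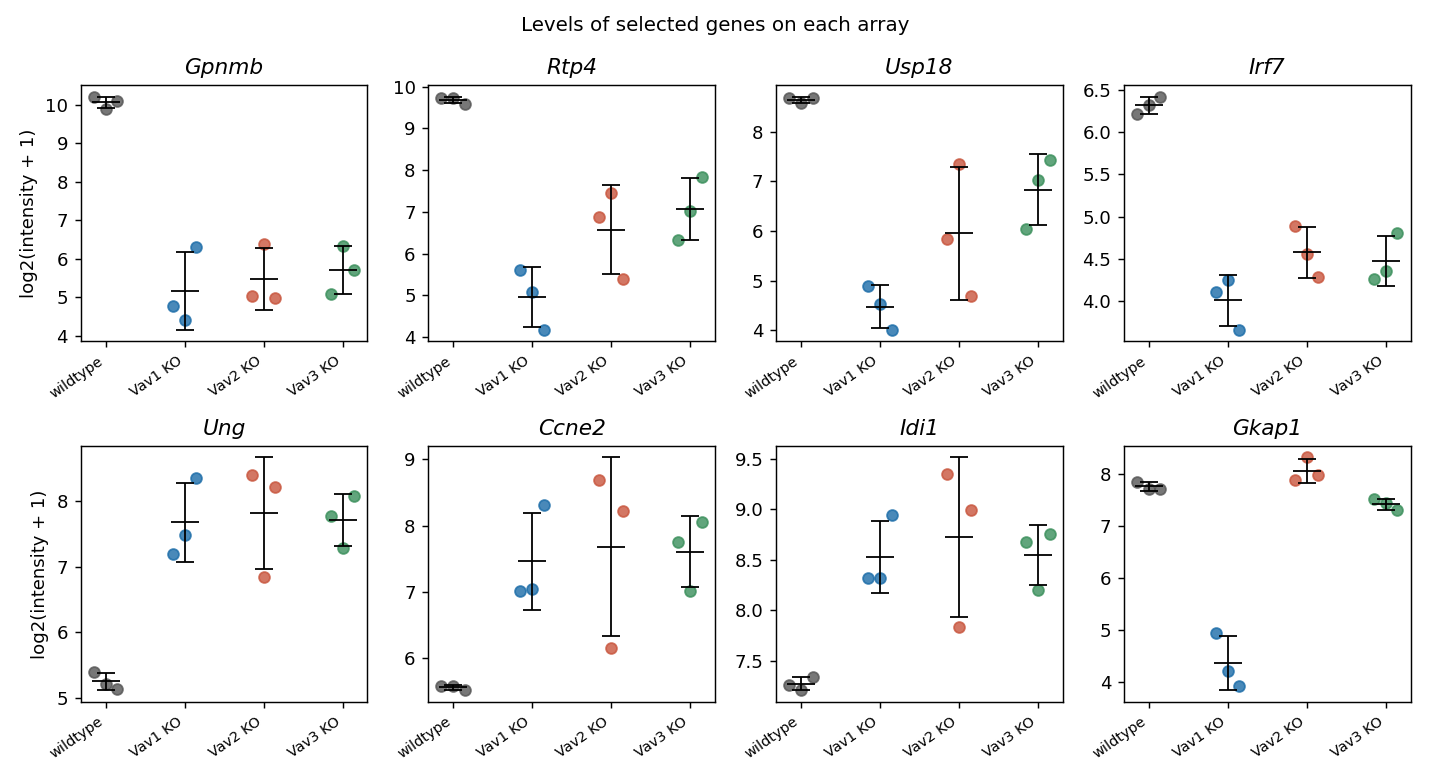
Level of 8 genes on each array as log2(intensity + 1) (y axis, not starting at 0) by group (x axis), with points for arrays and black marks for the mean and SD of 3 arrays. Gpnmb, Rtp4, Usp18 and Irf7 were lower and Ung, Ccne2 and Idi1 higher in each knockout than in wildtype cells, and Gkap1 averaged 20.4 intensity units in the Vav1 knockout against 269 and 171 in the Vav2 and Vav3 knockouts.

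The knockouts were then compared directly with each other. Gkap1, which encodes a protein that binds cGMP-dependent protein kinase, was at 20.4 ± 8.09 in the Vav1 knockout and 269 ± 44.9 in the Vav2 knockout (SD, n = 3 each). It was at 171 ± 12.3 in the Vav3 knockout and 217 ± 12.3 in wildtype cells. Gkap1 was the 1 gene called between the Vav1 and Vav2 knockouts, with a log2 difference of -3.71 ± 0.21 (SE, adjusted p = 3.22e-05). Between the Vav1 and Vav3 knockouts, 3 genes were called. These were Gkap1 (-3.07 ± 0.21, adjusted p = 2.34e-04), Vav3 (2.13 ± 0.20, adjusted p = 0.00256) and the interferon-induced gene Epsti1 (-1.58 ± 0.19, adjusted p = 0.0240). Between the Vav2 and Vav3 knockouts Vav3 was the 1 called gene (2.08 ± 0.20, adjusted p = 0.00668). Vav1 itself was not called between the Vav1 knockout and either other knockout. Yet it averaged 30.1 in the Vav1, 148 in the Vav2 and 165 in the Vav3 knockout, so real differences can be missed here. At an unadjusted p under 0.05, limma gave 335, 818 and 531 genes in these 3 comparisons. Chance alone would pass a share of 0.05 of the 11962 tested genes, which is more than 335 or 531 and fewer than 818. Few calls do not show that the knockouts act alike, and without both Vav1_KO 3 and Vav2_KO 2, a choice made after seeing the data, the counts were 2088, 59 and 582. For Vav1 against Vav2 the count was 9 without Vav1_KO 3 and 9 without Vav2_KO 2. For Vav1 against Vav3 it was 9 without Vav1_KO 3 and 14 without Vav3_KO 1, and 982 with array weights. For Vav2 against Vav3 it was 2 without Vav2_KO 1, 2 without Vav2_KO 3, 7 without Vav3_KO 1, 0 without Vav3_KO 2 and 0 without Vav3_KO 3, and 0 when only their 6 arrays were fitted, with or without a replicate block. In simulated data, 30 of 183, 38 of 194 and 31 of 187 calls between knockouts were false.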

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

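The tests of shared wildtype arrays, RNA degradation, separate processing, wildtype cells in the cultures and swapped labels were chosen after the values they use had been seen.

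The direct comparisons gave 5 differences between knockouts. Gkap1 was lower in the Vav1 knockout than in the Vav2 (log2 difference -3.71) and Vav3 knockouts (-3.07), Epsti1 was lower in the Vav1 than in the Vav3 knockout (-1.58), and Vav3 was higher in the Vav1 (2.13) and Vav2 (2.08) knockouts than in the Vav3 knockout. Among probe sets without a listed gene, 110 changed the same way in all 3 knockouts, 62 up and 48 down of 2185 above the filter. Of 45 bacterial control probe sets, which hold no cell RNA, 13 were higher on all knockout than on all wildtype arrays.

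The 1774 genes changed the same way in all 3 knockouts were weighed first. Simulated unchanged groups against the same wildtype arrays gave at most 0 such genes. Genes were drawn there independently with the spread between arrays, which argues only against such independent noise as the whole cause. The simulations hold no offset common to the 3 wildtype arrays and cannot weigh one. Of 100 regroupings of the 12 arrays, 1, the real one, gave as many, with 1 gene as the highest of the others. This argues against a chance assignment of single arrays to the groups. No other regrouping drawn kept the 3 wildtype arrays together as the control group. A chance difference of the wildtype samples as a whole therefore stays open. Separate processing of the wildtype arrays stays open. Of the 45 control probe sets, 16 (35.6%, against 0.909% by chance for 1 probe set) had all knockout arrays on 1 side of the wildtype arrays. The median difference was 0.292 log2 units among these 16 and 0.173 among all 45. Several of them share 1 transcript, so they are not independent. The share met the criterion written for separate processing after the values had been seen, but group and processing cannot be told apart without dates. RNA degradation was not settled either: the mean Gapdh 3' minus 5' log2 difference was 0.0150 higher in knockout than in wildtype arrays, the mean beta-actin value was lower (0.587 against 0.614), and the ranges overlapped for both. The 18S ribosomal RNA control read from 10.7 to 10.8 log2 units on the wildtype arrays, 10.6 on Vav2_KO 2 and from 10.9 to 11.8 on the other 8 knockout arrays, which also leaves a difference in the RNA or its processing open. A state that also differs between arrays of 1 genotype may contribute. The leading axis among arrays of the other 2 knockouts correlated over genes with the fold changes of the third at 0.598 or more. With that axis as a covariate, 2778, 1998 and 2462 genes were called, of which 1933, 1540 and 1818 were also called without it. The axis came from arrays of the same fit, and the median SE was lower with it in each comparison. Mean wildtype scores (-30.66, -26.23 and -30.01) lay below the lowest score of the knockout compared (-12.89, -21.23 and -12.37). The fit thus extended the trend beyond the arrays of that knockout. These counts therefore cannot weigh such a state. A common response to losing any Vav gene remains an untested alternative.

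The spread among knockout arrays was weighed next. Over genes changed in the other knockouts, the Vav1 knockout array nearest to wildtype lay 44.2% ± 1.91 (SE over genes) of the way from the farthest array to wildtype but kept 13.5% of wildtype Vav1 signal, and the Vav3 knockout array nearest to wildtype lay 42.1% ± 1.21 of the way with 18.5% of Vav3 signal, which argues against wildtype cells in those cultures as the whole cause. For the Vav2 knockout the nearest array, Vav2_KO 2, lay 68.8% ± 2.34 of the way, but genes lower in the other knockouts, whose level caps the wildtype share, read there at a median 47.0% of wildtype (95% interval 44.7 to 52.1), with 107 of 129 below 68.8%. This argues against wildtype cells as the whole cause. The single genes ranged from 6.72% to 119% of wildtype. Each gene caps the share by itself, so the lowest genes and not the median set the limit. The lowest value, of Gbp8, came from an intensity under the array median. Gpnmb, well above that median, read 82.8 on Vav2_KO 2 and from 947 to 1165 on the wildtype arrays. A share below such a limit stays open, as no Vav2 probe set passed the test between the Vav2 knockout and wildtype cells. The split of the Vav1 and Vav2 knockout arrays that exchanges Vav1_KO 3 with Vav2_KO 2 called 4230 genes, which points to a structure of the samples that is not the labelled genotype. Exchanged labels are argued against by the Vav1 intensity of Vav2_KO 2, which was 220.1 where the Vav1 knockout arrays read 36.4, 42.7 and 11.2.

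The low Gkap1 level of the Vav1 knockout was weighed last. It rests on 1 probe set, and 0 other Gkap1 probe sets were above the filter, so an artifact of that probe set stays open. The nearest tested genes on either side, Ubqln1 and Kif27, chosen after their values were seen, gave log2 fold changes of -0.08 (adjusted p = 0.365) and -0.03 (adjusted p = 0.837). An effect of losing Vav1 stays open and was not tested.

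For single comparisons of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05. Only the real split of the 10, counted as 1, gave as many calls for the Vav1, Vav2 and Vav3 knockouts against wildtype (2953, 2923 and 2476 genes, with 0 as the highest of the other splits in each). Between knockouts, 3 of 10 splits gave as many as the 1 gene called for Vav1 against Vav2 (highest other 4230), 1 of 10 as many as the 3 genes for Vav1 against Vav3 (highest other 1), and 3 of 10 as many as the 1 gene for Vav2 against Vav3 (highest other 1).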

How the results depend on the processing

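Alternatives added after seeing the data were no offset, group variances, a replicate block for Vav2 against Vav3 alone, and leaving out Vav1_KO 3 and Vav2_KO 2; all others were fixed before. The Vav1 and Vav3 levels kept their direction and stayed below the threshold of 0.05 in their own knockouts under every alternative run on them, and the adjusted p of the Vav2 level stayed above it (from 0.154 to 0.770). The ranges without 1 array cover, for each comparison, only the removal of arrays of its own groups, and for shared genes the removal of any array. The log2 fold changes ranged from -3.66 to -2.74 (Vav1), 0.10 to 0.29 (Vav2) and -2.51 to -2.44 (Vav3). Counts of changed genes ranged from 1380 to 2975 (Vav1), 1111 to 5397 (Vav2) and 829 to 1791 (Vav3), of shared genes from 598 to 3061, and between knockouts from 1 to 9 (Vav1 and Vav2), 2 to 14 (Vav1 and Vav3) and 0 to 7 (Vav2 and Vav3). The 3061 genes shared without Vav2_KO 2 were by definition also called in the Vav1 and Vav3 knockouts. The counts of these knockouts therefore exceeded their ranges given here, as all groups share 1 estimate of spread. Correlations ranged from 0.867 to 0.938, 0.862 to 0.914 and 0.890 to 0.937, and called lists from 15 to 19, 14 to 19 and 14 to 20. Fewer arrays leave less power, but the cause of the single shifts was not tested.

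A log2 fold change of at least 1 left 359, 360 and 263 genes and 192 shared, and treat against 0.5 left 72, 39, 30 and 25, as stricter thresholds must. An estimated correlation left 0 lists in each knockout, where fry called 20, 18 and 17. Fitting only the arrays of the groups compared gave 1544 genes for Vav2, 5439 for Vav3 and 0 between Vav2 and Vav3. Array weights gave 6642 genes for Vav1, 6568 for Vav3 and 982 between Vav1 and Vav3, with correlations of 0.831, 0.870 and 0.890. The median shift gave 2 genes between Vav1 and Vav2 and 6 between Vav1 and Vav3. Without both Vav1_KO 3 and Vav2_KO 2 there were 6181 genes for Vav2, 3100 shared, 2088, 59 and 582 between knockouts, and correlations of 0.813 (Vav1 and Vav2) and 0.863 (Vav1 and Vav3). Of the 1774 shared genes, 1757 were kept there, 1460 (of 2564) with array weights, 1328 (of 1499) under the median shift and 1770 (of 2644) with group variances. The causes were not tested. No called list changed direction under quantile normalization or the median shift, and 3 of 49 calls were lost under the latter.

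Of 3141 values of named genes under the alternatives, 2855 kept direction and side of the threshold, 286 lost the call, 0 gained one and 0 changed direction. Of the lost calls, 41, 54 and 52 were lost without WT 1, WT 2 and WT 3.

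In the comparisons other than Vav2 against Vav3, 5 of 15 same-number pairs correlated above 0.1, from -0.592 to 0.547, and not every array correlated best with its own number, so numbers did not pair those arrays. With the replicate block 3076, 3029 and 2570 genes were called and 1895 were shared, and the block moved no count by over 1.5 times. Between the Vav2 and Vav3 knockouts, 1 gene was called with the block over all arrays, and 0 with the block in a fit of these 6 arrays, as in that fit without it.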

Other observations

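Several lists were not called by camera in any of the 3 knockouts. Of 30 fatty acid and lipid droplet genes, 9, 10 and 7 rose and 2, 2 and 3 fell in the Vav1, Vav2 and Vav3 knockouts (10, 10 and 7 and 3, 2 and 3 adjusted over the list alone, camera adjusted p = 0.192, 0.149 and 0.481). The lipid synthesis genes Fads2 (1.41, 1.53 and 1.37), Fasn (1.34, 1.34 and 0.88) and Elovl6 (1.30, 1.33 and 1.06) rose, while Plin2, which coats lipid droplets, fell (-1.28, -1.31 and -1.18). Of 20 osteoclast genes, 2, 1 and 2 rose and 3, 2 and 3 fell (3, 1 and 2 and 4, 1 and 3 adjusted over the list alone, camera adjusted p = 0.297, 0.303 and 0.368), with the vacuolar ATPase subunit gene Atp6v0d2 lower in each (at least 1.04 lower in log2 units, at least 1.04 lower and at least 1.01 lower). Of 31 unfolded protein response genes, 0, 7 and 0 rose and 6, 3 and 4 fell (0, 9 and 0 and 6, 4 and 2 adjusted over the list alone, camera adjusted p = 0.789, 0.169 and 0.801), and in the Vav2 knockout the chaperone genes Sdf2l1 (1.26), Creld2 (1.17) and Calr (0.90) rose. The Vav2 knockout arrays were uneven, with Sdf2l1 at 2160, 627 and 1811 against 535 to 589 in wildtype cells. Sdf2l1 also read above wildtype on all Vav1 and Vav3 knockout arrays (899 to 1279). None of these chaperone genes was called between knockouts.

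Of 40 genes of tyrosine kinase signalling near Vav, 4, 3 and 3 rose and 6, 9 and 5 fell in the Vav1, Vav2 and Vav3 knockouts (4, 4 and 2 and 7, 10 and 4 adjusted over the list alone, camera adjusted p = 0.143, 0.0993 and 0.0966), with the kinase gene Csk higher in the Vav1 knockout (0.60) and Syk lower in the Vav3 knockout (-0.91). Of 31 Toll-like receptor pathway genes, 1, 0 and 0 rose and 3, 4 and 3 fell (0, 0 and 0 and 2, 4 and 3 adjusted over the list alone, camera adjusted p = 0.119, 0.0971 and 0.229). Of 18 chemokine genes, 0, 0 and 0 rose and 5, 4 and 3 fell (1, 0 and 0 and 6, 4 and 3 adjusted over the list alone, camera adjusted p = 0.0577, 0.0682 and 0.378). Of 13 chemoattractant receptor genes, 1, 2 and 1 rose and 2, 2 and 2 fell (1, 2 and 1 and 2, 2 and 2 adjusted over the list alone, camera adjusted p = 0.427, 0.599 and 0.970). Of 13 alternative activation genes, 2, 1 and 0 rose and 1, 2 and 3 fell (2, 1 and 1 and 1, 2 and 4 adjusted over the list alone, camera adjusted p = 0.752, 0.303 and 0.560). Of 16 liver X receptor target genes, 3, 3 and 1 rose and 2, 1 and 3 fell (3, 3 and 1 and 3, 4 and 3 adjusted over the list alone, camera adjusted p = 0.752, 0.405 and 0.272). Of 29 glycolysis and hypoxia genes, 3, 5 and 2 rose and 4, 3 and 5 fell (7, 9 and 3 and 4, 4 and 5 adjusted over the list alone, camera adjusted p = 0.752, 0.285 and 0.417). Of 21 antioxidant response genes, 4, 10 and 3 rose and 2, 1 and 2 fell (7, 10 and 4 and 3, 2 and 2 adjusted over the list alone, camera adjusted p = 0.427, 0.0682 and 0.667). Of 37 immediate early genes, 5, 2 and 5 rose and 3, 6 and 4 fell (5, 2 and 5 and 3, 4 and 4 adjusted over the list alone, camera adjusted p = 0.578, 0.0880 and 0.760). Of 36 cytosolic ribosomal protein genes, 1, 3 and 2 rose and 0, 0 and 0 fell (0, 3 and 1 and 0, 0 and 0 adjusted over the list alone, camera adjusted p = 0.942, 0.992 and 0.229). Of 53 actin and podosome genes, 6 rose and 12 fell in the Vav2 and 5 and 12 in the Vav3 knockout (8 and 12, and 5 and 14, adjusted over the list alone), without a call by camera (adjusted p = 0.169 and 0.0649). Of 21 matrix remodelling genes, 1 rose and 3 fell in the Vav2 and 0 and 3 in the Vav3 knockout (1 and 3, and 0 and 3, adjusted over the list alone), without a call by camera (adjusted p = 0.0880 and 0.159). Of 6 complement genes, 0 rose and 3 fell in the Vav2 and 0 and 2 in the Vav3 knockout (0 and 3, and 0 and 4, adjusted over the list alone), without a call by camera (adjusted p = 0.0880 and 0.0572). The sign of the median, the mean and the test differed for alternative activation markers (Vav1 and Vav3), glycolysis and hypoxia response (Vav1), unfolded protein response (Vav1 and Vav3), immediate early and serum response (Vav1 and Vav3), cytosolic ribosomal proteins (Vav1 and Vav2), T and natural killer lymphocytes (each knockout), B lymphocytes (Vav1), chemokines (Vav3), fibroblasts and stroma (Vav3). Markers of other cell types gave no call by camera. Of 7 markers of T and natural killer lymphocytes and 6 of B lymphocytes none was called (camera adjusted p = 0.846, 0.974 and 0.910, and 0.942, 0.686 and 0.513). Of 11 fibroblast markers, 0, 0 and 0 rose and 1, 1 and 1 fell (camera adjusted p = 0.427, 0.589 and 0.999). Of 10 dendritic cell markers, 0, 0 and 0 rose and 2, 1 and 2 fell (camera adjusted p = 0.194, 0.247 and 0.513), and fry called this list in each knockout. The lists called by fry and not by camera were, with fry adjusted p, chemokine (0.0135), osteoclast (0.0174), fatty acid (0.0138), p53 target (0.0371) and dendritic cell (0.00216) genes in the Vav1, chemokine (0.0157), matrix remodelling (0.0157), fatty acid (0.0157), antioxidant response (0.0117), complement (0.0305) and dendritic cell (0.0305) genes in the Vav2 and actin and podosome (0.0343), osteoclast (0.0262), matrix remodelling (0.0343), complement (0.0164), ribosomal protein (0.0391) and dendritic cell (0.0373) genes in the Vav3 knockout.

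Over the 6 arrays of the Vav2 and Vav3 knockouts, Vav1 level fell as the score on the leading axis among arrays of 1 genotype rose (Pearson r = -0.953, exact permutation p = 0.00417; Spearman r = -1, exact permutation p = 0.00278, the smallest that 6 arrays allow; two-sided). Without the 2 arrays farthest from the median score r was -0.858. Over the 6 arrays of the Vav1 and Vav2 knockouts, Vav3 level did likewise (r = -0.978, exact permutation p = 0.00417; Spearman r = -0.943, exact permutation p = 0.0167; r = -0.964 without the 2 farthest). The adjusted p over these 2 relations was 0.00417 for each r. The axis was built from the same arrays, the relations were chosen after the levels had been seen, and 3 arrays per genotype are too few for a value within each. With the Vav genes kept, such an axis held 70.7% of the variance within the Vav2 and Vav3 and 73.2% within the Vav1 and Vav2 knockouts. Other genes must follow it too, and their share was not computed, so nothing particular to Vav1 or Vav3 is shown. The permutations also treat arrays of 2 genotypes as exchangeable.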
